A study of Homo sapiens with 174 samples.

How the data were processed

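Poly(A) RNA from cortical brain organoids was captured with oligo-dT beads and made into libraries with the KAPA mRNA HyperPrep kit for a NovaSeq X sequencer, per the labels' protocols. The submitters' processing notes name STAR, an aligner, Salmon, a transcript quantifier, and the GRCh38 genome, without versions or roles. The annotation release, the strand setting and any filter are not given in the sources used here. The design text speaks of 179 libraries, of which 174 were analysed and 5 were not analysed here. The authors deposited whole-number counts of reads per gene for 38592 genes, not normalized, and these were the main values. They also deposited estimated counts per gene, not whole, which were rounded before use as an alternative, and TPM per gene and per transcript. A further deposited table counts reads outside features, multimapping or unmapped. These entries stayed out of library sizes and tests. Reads outside features made up a median of 16.2% of reads in the LHX9 collection and 48.6% in OTX1 day 9. Such reads, and multimapping reads (a median of 22.8% in the LHX9 collection and 4.54% in OTX1 day 9), lower the depth left for genes. Where the reads outside features lie was not examined. Symbols were taken from the reference annotation, GENCODE 29 on GRCh38, for 25647 genes, and 34390 genes had coordinates there. Genes without them entered the tests but not the analyses by position.

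Samples were grouped by target, day and editing strategy from the labels, and replicates were named by clone from the titles. The labels of some samples disagree: a time field gives day 6 for LHX5 libraries titled day 5, and clone names differ between titles and library names for RFX4 day 9 and for 1 FEZF2 day 8 exon clone. Titles were used. No pair of replicates agreed within sampling noise: over 159 pairs, the lowest chi-square per degree of freedom was 2.87. Library names show that RFX4 day 9, LHX5 day 6 and FEZF2 day 8 were sequenced apart from the earlier days of their series, and every knockout comparison was made within 1 day.

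Counts were analysed with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr (minimum count 10, minimum total 15), robust quasi-likelihood fits and Benjamini-Hochberg adjustment with a threshold of 0.05. For each target, the knockout effect was the mean of the full, exon and stop groups minus wild type on the last day collected. Editing strategies were compared in the same fit by an F test with 2 degrees of freedom. Later and earlier days prepared together were compared with strategy as covariate. Where a collection had 1 wild-type library, the fit pooled the spread between clones, and that library was assumed to vary like the clones within a strategy. This holds for RFX4, OTX1, PAX6, LHX9 and the earlier days of FEZF2 and LHX5. A negative log2 value means lower in knockouts, or lower on the later day. CPM of a targeted gene in its own collections, and all CPM of wild-type libraries pooled by day, were computed on plain library sizes. All other CPM, among them those of targeted genes over time, were on TMM-scaled sizes.

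A set of 36 gene lists, covering regional identities, cell types, signalling pathways and stress, was tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. DDX58 of the interferon list was not in the table. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. For knockouts, the rule named the target, its relatives, and the 8 higher and 8 lower genes with the largest change. These had to pass the threshold, reach 5 CPM and have all knockout libraries on 1 side of wild type. Up to 3 members of each list with at least 2 passing members were added. For strategies it named the target, neighbours that passed and the 8 largest spreads. For time it named the 6 largest changes each way and list members. Genes lacking a symbol, with clone-based or LINC names, or Y-linked were left out of the largest changes. Genes named outside the rule are stated as such. A few genes that the rule named are not reported here. Members of lists adjusted over the list alone are named for the lists described.

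Neighbouring genes were those within 500 kb of an edited site. The edited intervals come from the labels, in GRCh38 coordinates, and exons, coding bases and untranslated regions from GENCODE 29. The full intervals hold 100% of the coding bases of FEZF2, LHX5 and LHX9, 93.7% of PAX6, 87.1% of OTX1 and 70.7% of RFX4, in transcripts ENST00000283268, ENST00000261731, ENST00000367387, ENST00000640368, ENST00000282549 and ENST00000392842. Chromosome windows of 10 Mb with at least 20 genes were compared between libraries, and list levels per library used log2 CPM with a prior count of 2.

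Most clones were collected on both days of a time comparison. The clone name marks the same edited line, so clones pair the samples by design. Deviations of a clone on the earlier and later day correlated with a median r of 0.175 in LHX5, 0.217 in RFX4 and 0.218 in OTX1, but -0.00162 in FEZF2, across genes. Pairs over 0.1 numbered 8 of 9, 6 of 9, 5 of 6 and 4 of 9. A fit with the line as a block was run as an alternative.

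Other alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, the Salmon counts, each strategy alone, each other day, knockouts only, all days in 1 fit, wild-type libraries of other collections and leaving out each library in turn. Alternatives with the share of reads outside features, as a covariate or as a filter at 30%, were added after the data were seen. DESeq2 was run on the last day of each target only. On simulated counts with 200 changed genes, 2-fold changes were called in 91% of cases for the FEZF2 knockout comparison, 82.1% for LHX5, 68.7% for RFX4 and PAX6, 67.2% for OTX1 and 49.3% for LHX9. The comparisons over time called at least 98.5% of 2-fold changes. The simulation drew independent counts at the fitted dispersions, with the same change in every changed library, for genes of at least 1 CPM. It held no structure shared by libraries, such as lane or the share of reads outside features. The shares may therefore be too high for these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.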

Results

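The data were RNA-seq gene counts from cortical brain organoids, 3-dimensional neural cultures patterned toward dorsal forebrain. The organoids were grown from KOLF2.2J, a human induced pluripotent stem cell line, and from edited lines made from it. Each edited line carried a knockout of 1 of 6 transcription factor genes: FEZF2, LHX5, RFX4, OTX1, PAX6 or LHX9. Every gene was disrupted by 3 strategies: deletion of the coding region (full), deletion of a critical exon (exon) or insertion of a termination codon (stop). Each strategy was represented by 3 clones on each day. FEZF2 lines were collected on days 5, 6, 7 and 8, LHX5 lines on days 3, 4, 5 and 6, RFX4 lines on days 6, 7, 8 and 9, and OTX1 lines on days 7, 8 and 9. PAX6 lines were collected on day 7 and LHX9 lines on day 14. The 174 libraries held 153 knockout and 21 wild-type samples from 64 edited clones. Most collections had 1 wild-type library, whereas FEZF2 day 8 and LHX5 day 6 had 3. Reads assigned to genes ranged from 10701854 to 51835433 per library, with a median of 28477329.5. OTX1 day 8 was the shallowest collection (median 16034413) and LHX5 day 3 the deepest (median 38928901.5). The labels give no separate cultures for wild-type libraries, so their spread may be technical, whereas knockout replicates were separate clones.

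In the wild-type line, the pluripotency factor POU5F1 was at 1194 CPM on day 3 (n = 1), 389 ± 115 on day 6 (SD, n = 5), 26.6 ± 18.7 on day 8 (n = 5) and 1.27 on day 14 (n = 1). LHX5, a LIM homeodomain factor of early forebrain, was at 3.55 CPM on day 3, 31.6 ± 11.3 on day 6 and 159 ± 31 on day 7 (n = 4). OTX1, a homeobox factor of forebrain and midbrain, was at 3.03 ± 0.91 CPM on day 6 and 105 ± 11 on day 8. PAX6, a paired-box factor of dorsal telencephalic progenitors, was at 1.67 ± 1.95 CPM on day 6, 198 ± 21 on day 8 and 497 on day 14. FEZF2, a zinc-finger factor of anterior forebrain, was at 1.82 ± 1.79 CPM on day 6, 12.9 ± 7.2 on day 8 and 78.8 on day 14. RFX4, a winged-helix factor, was at 0.825 ± 0.404 CPM on day 6 and 73.6 on day 14. LHX9, another LIM homeodomain factor, was at 0.893 ± 0.146 CPM on day 7 and 11.4 on day 14. These values pool collections made for different targets, which differ in sequencing batch, so no test was made across them.

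**Figure D1:**
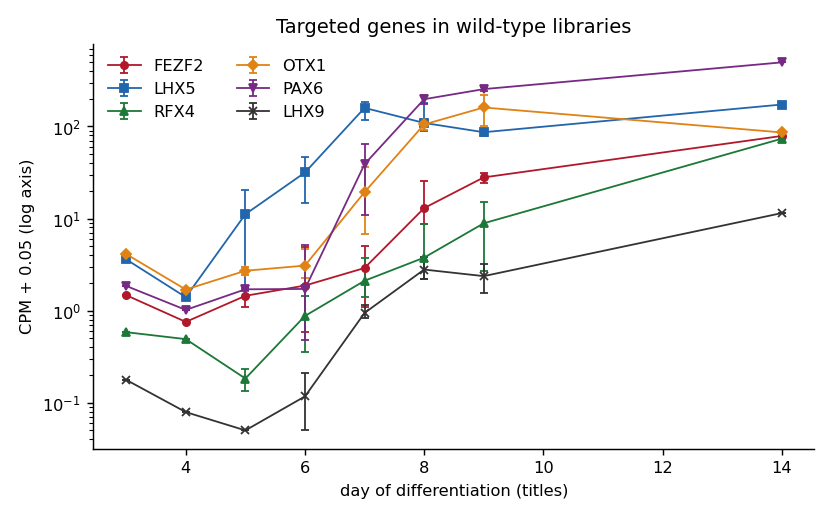
Level of the 6 target genes in wild-type libraries by day, as mean CPM with bars from lowest to highest library, on a log axis after adding 0.05. PAX6 was at 1.67 CPM on day 6 and 497 on day 14, and LHX5 at 3.55 on day 3 and 159 on day 7.

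The targeted gene was examined in every group first. Full deletion of FEZF2 (chromosome 3, minus strand, GRCh38 62369908 to 62372871, exons 2 to 5) left 2.58 ± 0.65 CPM of FEZF2 on day 8, against 9.44 ± 0.65 in wild type (SD, n = 3 each). The log2 difference was -1.92 (SE 0.17, edgeR adjusted p = 7.28e-05). The exon strategy (62371886 to 62372981, exon 2) gave 8.96 ± 1.11 CPM and the stop strategy (62372632 to 62372634, exon 2) 15.3 ± 2.2 CPM. Their differences from wild type, -0.07 (SE 0.15) and 0.65 (SE 0.14), did not pass over all genes (edgeR adjusted p = 0.940 and 0.455), while stop lines exceeded full lines by 2.56 (SE 0.17, edgeR adjusted p = 6.55e-07). All 3 full clones shared a sequencing lane without wild-type libraries, so their difference from wild type on day 8 is also one between lanes. Exon clone A11, from that lane, had 8.58 CPM. On day 7 all libraries shared a single lane. FEZF2 was then at 0.912 ± 0.286 CPM in full, 4.36 ± 0.88 in exon, 10.8 ± 3.0 in stop and 3.34 in the single wild-type library. Stop lines exceeded full lines by 3.54 (SE 0.25) on that day. This argues against lane as the source of the day 7 difference between strategies.

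LHX9 was also lowest in full deletion lines on day 14. Full deletion (chromosome 1, plus strand, 197917782 to 197932159, exons 1 to 5) left 1.75 ± 0.29 CPM, against 11.4 in the wild-type library (log2 -2.66, SE 0.30, edgeR adjusted p = 0.00362). The exon lines (197921239 to 197921798, exon 3) held 9.52 ± 1.23 CPM and the stop lines (197921500 to 197921502, exon 3) 5.74 ± 1.65. Exon lines exceeded full lines by 2.44 (edgeR adjusted p = 0.000655), while the excess of stop lines missed the threshold (1.73, edgeR adjusted p = 0.0555). RFX4 was not lowest in full lines on day 8, at 1.70 ± 1.33 CPM with a highest library of 3.12. Exon lines held 1.67 that day, stop lines 1.42 and the wild-type library 3.07. On day 9 RFX4 was at 0.422 ± 0.188 CPM after full deletion (chromosome 12, plus strand, 106686784 to 106750903, exons 6 to 17). Exon lines (106696247 to 106696488, exon 8) held 2.03 ± 1.10, stop lines (106696367 to 106696369, exon 8) 2.16 ± 0.67 and the wild-type library 2.63. The full difference of -2.62 (SE 0.55) did not pass after adjustment (edgeR adjusted p = 0.756).

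Gene counts of the other 3 targets did not differ from wild type past the threshold after full deletion. LHX5 full deletion (chromosome 12, minus strand, 113463097 to 113471510, exons 1 to 5) removes 100% of the coding bases but 44.7% of the exon bases. LHX5 on day 6 was at 26.3 ± 15.4 CPM in full lines, 15.7 ± 4.7 in exon lines (113469096 to 113469370, exon 2), 29.3 ± 5.2 in stop lines (113468274 to 113468276, exon 3) and 32.3 ± 2.3 in wild type. OTX1 full deletion (chromosome 2, plus strand, 63053021 to 63056206, exons 3 to 5) removes 32.3% of the exon bases. OTX1 on day 9 was at 256 ± 59 CPM in full, 333 ± 25 in exon (63054034 to 63054216, exon 4), 275 ± 13 in stop (63055621 to 63055623, exon 5) and 221 in the wild-type library. PAX6 full deletion (chromosome 11, minus strand, 31790627 to 31806601, exons 4 to 13) removes 18.3% of the exon bases of transcript ENST00000640368. PAX6 on day 7 was at 65.8 ± 7.1 CPM in full, 29.1 ± 6.0 in exon (31793364 to 31794908, exons 9 to 12), 20.6 ± 13.9 in stop (31794736 to 31794738, exon 9) and 42.8 in the wild-type library. None of these differences from wild type passed (edgeR adjusted p from 0.286 upward). Counts from untranslated exons outside a deletion do not check the deletion, so transcripts with at least 60% of their exon length inside it were examined. Those of PAX6 summed to 0.214 ± 0.151 TPM in full lines and 11.03 in wild type. The one such OTX1 transcript was at 0 in all full lines and 0.821 TPM in wild type on day 9. It was also low in exon lines (0.132 TPM), though not in stop lines (1.75 TPM), and at 0 in wild type on day 7. It therefore checks the OTX1 deletion only weakly, and LHX5 had no such transcript. Gene counts also do not check the stop edits, or the exon deletions of the other 5 targets, which hold 4.1% to 7.6% of the exon bases. The FEZF2 exon deletion holds 43.9%. Exon lines held 0.181 ± 0.188 CPM of FEZF2 against 1.75 in wild type on day 5 and 0.564 ± 0.206 against 1.78 on day 6, but 4.36 against 3.34 on day 7. None of these differences passed (edgeR adjusted p = 0.109, 0.244 and 0.562), and their direction turned between days. The LHX5 full label also has no check in these values.

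**Figure D2:**
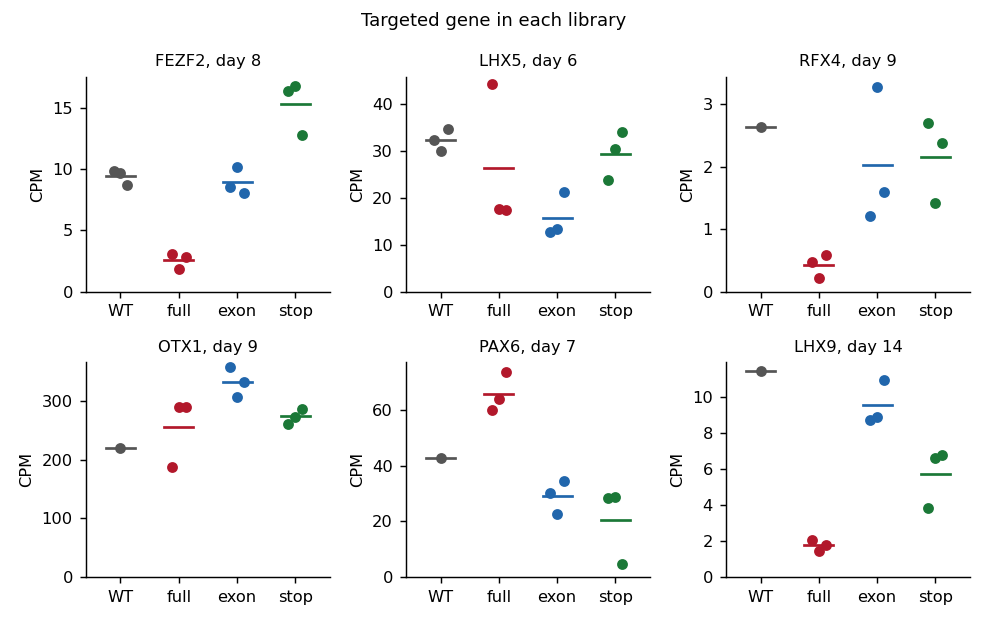
CPM of the targeted gene on the last day of each series, with 1 panel per target, points for single libraries and a line for each group mean. Full deletion lines lay lowest for FEZF2, RFX4 and LHX9, but highest for PAX6 (65.8 CPM against 42.8 in the wild-type library).

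LHX5 knockouts on day 6 had lower levels of 2 WNT receptors and higher levels of NOTCH1 and LFNG than wild type. FZD5 and FZD8, both WNT receptors, were lower by -0.44 (SE 0.07, 131 ± 11 against 178 ± 12 CPM) and -0.47 (SE 0.08, 25.3 against 34.9 CPM). NOTCH1 rose by 0.47 (SE 0.08, 89.4 ± 14.6 against 63.9 ± 4.5 CPM), and LFNG, a glycosyltransferase that modifies Notch, rose by 0.77 (SE 0.10, 134 ± 16 against 78.7 ± 7.8 CPM; n = 9 and 3). HAS3, a hyaluronan synthase, rose by 0.96 (SE 0.14), the BMP pathway modulator KCP by 0.69 (SE 0.11) and the pacemaker channel HCN4 by 0.52 (SE 0.08). CYP1B1, PTPRN2, LYN and RAB15 were also higher, by 0.66, 0.57, 0.52 and 0.48. C6orf141 was lower by -0.96 (SE 0.14, 34.5 ± 8.3 against 66.2 ± 2.7 CPM), and MYCBPAP, SLC13A3 and SLC13A4 were lower by -0.75, -0.50 and -0.44. The metallothionein genes MT1E, MT1G and MT1X were lower by -3.70, -3.23 and -1.63. These 3 low genes fell outside the naming rule and were chosen after their values were seen, and near-identical family members can share their reads. In all, 23 of 21467 genes passed, 10 higher and 13 lower (edgeR adjusted p from 0.0166 to 0.0467). On earlier days, with 1 wild-type library each, several directions turned without passing: NOTCH1 was at -0.16 and -0.12 and LFNG at -0.03 and -0.09 on days 4 and 5. HAS3, KCP, HCN4, PTPRN2, LYN and RAB15 also lay below 0, and MYCBPAP, SLC13A3 and SLC13A4 above 0, on at least 1 earlier day. LHX5 itself (-0.44, SE 0.27) and its relative LHX1 (0.66, SE 0.26) did not pass. DESeq2 called 252 genes, 157 higher and 95 lower. Reads outside features made up 23.3% to 46.3% of reads in knockout libraries and 37.7% to 43.6% in wild type. With this share as a covariate edgeR called 95 genes, and HCN4 and C6orf141 were no longer among them (edgeR adjusted p = 0.0741 and 0.136). Without the 3 libraries under 30% (full B02, full E04 and exon A01) it called 0. Against wild type, full clones alone gave 4291 genes, exon clones 0 and stop clones 212. The count depended on single libraries: it was 4361 without exon clone B05, 37 without exon E03, 35 without exon A01, 9 without stop A10 and 8 without full F01. It was 4 or lower without full B02 (1), full E04 (2), stop B10 (2), stop A11 (0), WT 1 (3), WT 2 (0) or WT 3 (0).

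Markers of the anterior neural plate, the future forebrain, were lower in LHX5 knockouts. On day 6, 12 of 14 members lay below 0, none passed over all genes, and 5 were lower when adjusted over the list alone. SIX3, a forebrain homeobox factor, was at -1.37 (SE 0.27), FEZF2 at -1.59 (SE 0.44), the WNT and FGF antagonist SHISA2 at -1.01 (SE 0.30) and OTX1 at -0.89 (SE 0.26), whereas SFRP2 was at 0.62. Levels were low: in the 5 wild-type libraries of day 6 over all series, SIX3 lay at 0.935 to 4.35 CPM. FEZF2 lay at 0.536 to 4.90 CPM and OTX1 at 2.20 to 4.59 CPM there. The list passed camera with the preset correlation (adjusted p = 5.79e-05), but not with an estimated one (adjusted p = 0.0641 with an estimated correlation). On days 3, 4 and 5 the list was lower by means of -1.22, -1.03 and -0.66 (adjusted p = 0.0611, 0.00365 and 0.241 with an estimated correlation). On day 3, SIX3 fell by 3.27 (SE 0.43, edgeR adjusted p = 0.0171, 0.468 against 3.82 CPM) and FEZF2 by 3.75 (SE 0.55, edgeR adjusted p = 0.0227). LINC01833 and GAD1 were the other genes called that day, at -2.78 and -1.87. On day 4, SIX3 (-3.80, edgeR adjusted p = 0.00737), DLK1 (-2.56, edgeR adjusted p = 0.0151) and FEZF1-AS1 (-2.22, edgeR adjusted p = 0.0367) were lower. These named genes of days 3 and 4 were chosen after their values were seen. FEZF2 was at 1.42 CPM in the wild-type library of day 3. Across 14354 genes outside the list, which are not independent replicates, the day 6 difference correlated with the change from day 5 to 7 in the FEZF2 series at r = -0.239. Only 1 wild-type library stood on each of days 3 to 5, and it was assumed to vary like clones within a strategy. The wild-type library of day 5 stood apart, with 13.5% of reads outside features against 15.6% to 19.1% in knockouts and 8.17% mitochondrial reads against 4.76% to 6.56%. That of day 4 held the highest mitochondrial share of its collection, 6.05%. On day 5 edgeR called 0 genes, with 1204 at an unadjusted p under 0.05; DESeq2 was not run on that day.

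**Figure D3:**
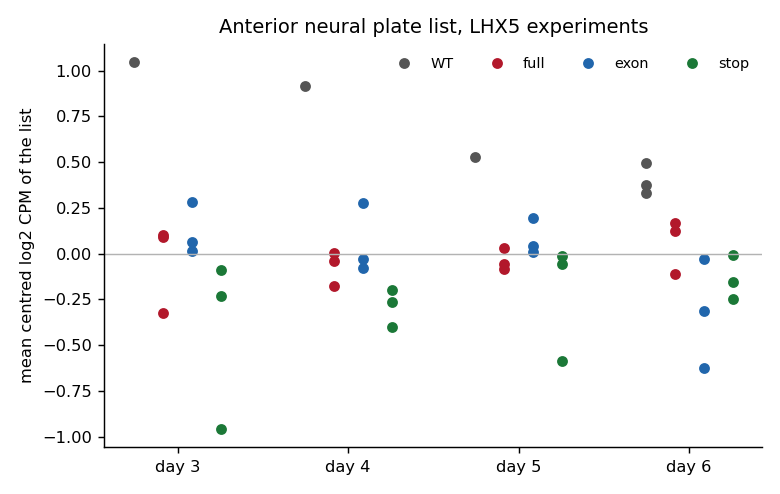
Mean centred log2 CPM of the anterior neural plate list in each LHX5 series library by day, for wild type and the 3 knockout strategies. All 9 knockout libraries lay below wild type on each day, and the fitted log2 differences averaged -1.22, -1.03, -0.66 and -0.54 over the members tested on days 3 to 6.

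Of 14 Notch pathway genes in LHX5 knockouts on day 6, 11 lay above 0, 2 passed over all genes and 6 were higher when adjusted over the list alone, including the effector HES5 (1.11, SE 0.30). The Notch list passed camera (adjusted p = 6.92e-05), and gave adjusted p = 0.0554 with an estimated correlation. Cholesterol synthesis genes lay above 0 in 19 of 20 cases, with 0 called over all genes by edgeR and 17 adjusted over the list alone. HMGCS1 was at 0.56 (SE 0.13) and SQLE at 0.38 (SE 0.07). That list passed camera (adjusted p = 2.30e-14) and gave adjusted p = 0.175 with an estimated correlation. Of 20 FGF and ERK response genes, 8 were higher and 2 lower when adjusted over the list alone, among them ETV4 (1.07, SE 0.25) and DUSP4 (-0.53). Its camera result (adjusted p = 0.00168) was not kept either (adjusted p = 0.495 with an estimated correlation), nor with the share of reads outside features as a covariate.

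OTX1 knockouts on day 9 showed lower GRIK3, a kainate receptor subunit, by -1.88 (SE 0.21, edgeR adjusted p = 0.00105), at 7.17 ± 2.01 CPM (n = 9) against 26.1 in the single wild-type library. MFAP3L was lower by -1.18 (SE 0.13, edgeR adjusted p = 0.000971), DDIT4L, a regulator of mTOR signalling, by -1.05 (SE 0.13, edgeR adjusted p = 0.00225) and the histone gene H2BC21 by -0.59 (SE 0.09, edgeR adjusted p = 0.0322). PGM5 was also lower (-2.80, SE 0.46, edgeR adjusted p = 0.0352), though outside the naming rule. Higher values of WDPCP (1.20) and ENSG00000286480 (2.03) came from full deletion clones, and histone genes of near-identical sequence can share reads. The 7 genes were among 21856 tested, and DESeq2 called 16. None of 14 Notch genes lay above 0, including HEYL (-1.01, SE 0.26), HES4 (-0.85, SE 0.22) and LFNG (-0.51, SE 0.16), which were lower adjusted over the list alone but not over all genes. The list passed camera (adjusted p = 1.98e-09), with adjusted p = 0.530 with an estimated correlation. OTX2, the paralog, was at -0.03 and OTX1 itself at 0.35 (SE 0.22). The lone wild-type library was assumed to vary like clones within a strategy. The count was 44 without full clone D02, 17 without full E06 and 12 without A08, and stop clones alone gave 107. GRIK3 was at 0.18 on day 7 and H2BC21 at 0.23 on day 8, neither past the threshold. On day 8, GCNT1 (-0.75, 39.9 against 67.2 CPM) and AGBL1 (-2.10) were lower. The wild-type library of day 8 stood apart, with 54.8% of reads outside features against 39.5% to 49.0% in knockouts and 3.84% of reads in ribosomal protein genes against 4.36% to 5.03%. On day 7 edgeR called 0 genes (555 at an unadjusted p under 0.05).

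No single gene passed over all genes in FEZF2 knockouts on day 8. Of 15 diencephalon and midbrain genes, 14 lay above 0 and 8 were higher adjusted over the list alone. The midbrain signal WNT1 was at 1.31 (SE 0.27) and the sensory neuron factor POU4F1 at 0.90 (SE 0.18), each above every wild-type library in all 9 knockouts. BARHL1 was at 0.91 and PAX2 at 0.50. The list passed camera (adjusted p = 1.20e-09), and gave adjusted p = 0.0948 with an estimated correlation. Of 20 anterior plate genes, 7 lay above 0 and 4 were lower adjusted over the list alone: LHX2 (-0.60, SE 0.19), RAX (-0.40), HESX1 (-0.33) and FEZF2 itself (-0.45, SE 0.12). Its camera adjusted p = 0.0222 became adjusted p = 0.561 with an estimated correlation. On days 5, 6 and 7, with 1 wild-type library each, the list averaged -0.84, -0.25 and 0.21. FEZF1, the paralog, was at -0.07 on day 8. edgeR called 0 of 20396 genes, with 1806 at an unadjusted p under 0.05, DESeq2 called 27 (23 higher, 4 lower), and limma voom over all days 3. With the share of reads outside features as a covariate edgeR called 8. Within the lane that held the wild type, edgeR also called 0, and without wild-type library 3 it called 191.

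On earlier FEZF2 days the knockouts stood against 1 wild-type library. On day 5, 304 genes were higher and 873 lower, among them 21 of 24 ribosomal protein genes (mean -0.37, adjusted p = 0.372 with an estimated correlation for the list). The wild-type library of day 5 stood apart from the 9 knockouts, with 13.7% of reads outside features against 17.1% to 22.7% and 4.93% of reads in ribosomal protein genes against 3.72% to 4.30%. Days 6 and 7 each had 1 gene called, ENSG00000260834, at -2.63 and -3.48.

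In RFX4 knockouts on day 9 no gene passed. Of 19 FGF and ERK response genes, 18 lay above 0, including the immediate early gene FOS (1.11, SE 0.39), the ETS factor ETV4 (0.94, SE 0.33) and the ERK inhibitor SPRY4 (0.92), but none passed adjusted over the list alone either. The list passed camera (adjusted p = 4.45e-09) and gave adjusted p = 0.235 with an estimated correlation. All 6 ventral telencephalon genes lay above 0 (adjusted p = 0.293 with an estimated correlation). RFX4 was at -1.10 (SE 0.45), RFX3 at -0.09, RFX2 at -0.03 and RFX1 at 0.03. edgeR called 0 of 21818 genes, with 542 at an unadjusted p under 0.05, and DESeq2 and limma voom over all days each called 1. Without C06 edgeR called 13, and full clones alone against wild type gave 405 (207 higher, 198 lower). On day 8, ANKRD28 was lower by -1.01 (52.7 ± 3.3 CPM against 106, edgeR adjusted p = 3.80e-05). On days 6 and 7 edgeR called 0 genes, with 392 and 442 at an unadjusted p under 0.05.

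PAX6 knockouts on day 7 had all 13 Notch genes above 0 (mean 0.38), with none called over all genes or adjusted over the list alone. The camera adjusted p was 0.000733, and adjusted p = 0.420 with an estimated correlation. PAX6 was at -0.34, PAX3 at 0.32 and PAX2 at 0.55. edgeR called 0 of 22439 genes, with 370 at an unadjusted p under 0.05, and DESeq2 called 0. Adding wild-type libraries of other collections, which differ in batch, gave 1023 genes.

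In LHX9 knockouts on day 14, the oldest organoids, 18 of 22 neuron genes lay above 0, with STMN2, a microtubule regulator of growing axons, at 0.78 (SE 0.20), the neurofilament gene NEFM at 0.86 and INA at 0.57. Adjusted over the list alone, 1 was higher and 1, LHX9 itself, lower, and over all genes none passed. The list passed camera (adjusted p = 2.05e-08) and gave adjusted p = 0.615 with an estimated correlation. Of 18 neurogenesis genes, 16 lay above 0, among them INSM1 at 1.01 (adjusted p = 0.926 with an estimated correlation). LHX9 was at -1.27 (SE 0.26) and LHX2 at -0.00. edgeR called 0 of 20835 genes, with 322 at an unadjusted p under 0.05, and DESeq2 called 1. Without stop clone A09 edgeR called 6, and exon clones alone gave 55. That library stood apart on chromosome 20, as the plot of chromosome 20 shows.

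**Figure D4:**
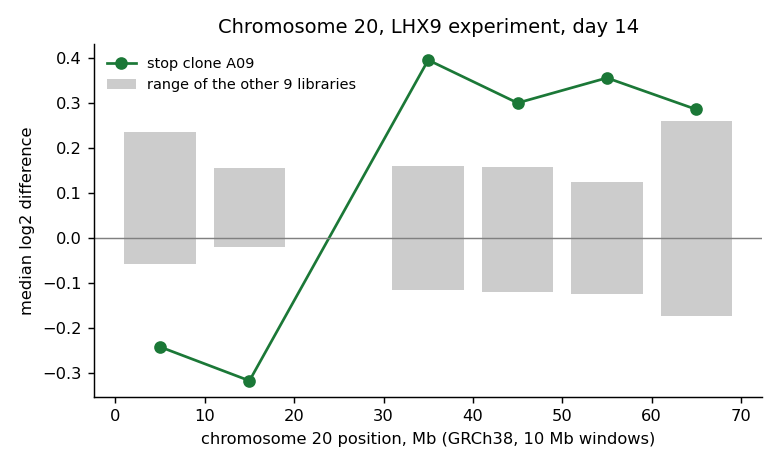
Difference of the LHX9 stop A09 library from the other 9 libraries in 10 Mb windows of chromosome 20, in log2, with the range of those libraries in grey. Windows from 0 to 20 Mb lay at -0.24 and -0.32 and windows from 30 to 70 Mb between 0.29 and 0.39.

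The 3 editing strategies were compared to ask whether the kind of edit changes the readout. On the last day collected, edgeR called at most 2 genes for each target. The FEZF2 count was 586 with knockout libraries alone, and on earlier FEZF2 days it was 37 (day 5), 0 (day 6) and 109 (day 7). On the last FEZF2 day, all full clones and exon A11 ran in another lane than the other knockouts. Strategy and lane therefore overlap in the FEZF2 counts of that day. In OTX1 lines on day 9, WDPCP, a planar cell polarity gene downstream of OTX1 (chromosome 2, 63121383 to 63827843), was at 158 ± 15 CPM in full lines, 29.2 in exon, 22.2 in stop and 20.3 in wild type (edgeR adjusted p = 7.46e-11). In Salmon counts the log2 difference of full lines from the other knockouts turned to -0.30 and did not pass. ENSG00000286480 was at 71.6 CPM in full, 4.84 in exon and 2.14 in stop (edgeR adjusted p = 8.59e-14). Its difference was kept in Salmon counts, at 46.6 CPM in full lines against 1.75 in the other knockouts (log2 4.90, SE 0.13). In LHX5 lines, ZNF528 was at 28.0 ± 2.9 CPM in full, 53.5 ± 8.1 in exon and 51.9 ± 4.6 in stop (edgeR adjusted p = 0.0422). In RFX4 lines, ENSG00000288595 was at 0.0384 CPM in exon, 4.11 in full and 2.75 in stop (edgeR adjusted p = 0.000117). FEZF2 in FEZF2 lines (edgeR adjusted p = 3.29e-06) and LHX9 in LHX9 lines (edgeR adjusted p = 0.00308) were the only genes called there. In PAX6 lines edgeR called 0 genes, with 696 at an unadjusted p under 0.05, and DESeq2 called 2. DESeq2 called 219 for FEZF2, 15 for LHX5, 47 for RFX4, 37 for OTX1 and 4 for LHX9. With the share of reads outside features as a covariate, edgeR called 6 for FEZF2, 30 for LHX5 and 6 for RFX4. The counts moved with single clones: OTX1 gave 178 without full E06 and 4 without D02, and RFX4 gave 458 without B12, 27 without C06, 9 without A09, 5 without B08 and 3 without C08. FEZF2 gave 4 without B11 and 2 without D04, G09 or A11. LHX5 gave 7 without B05, 2 without A01 or E03, and 0 without B02, E04, F01, A10, A11 or B10. PAX6 gave 2 without A11 and 1 without C03, and LHX9 gave 0 without any of full A01, A04 or B02.

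Of the earlier days of the OTX1 series, days 7 and 8 each had 10 genes called between strategies. HESX1, an anterior homeobox gene, was at 22.6 CPM in full, 11.5 in exon and 13.4 in stop on day 8. On day 7, EOMES, a T-box factor, was at 0.304 CPM in full against 2.86 and 2.08 (edgeR adjusted p = 0.0279), and SLITRK2 was at 0 against 1.32 and 1.33 (edgeR adjusted p = 0.00143). These genes of earlier days were chosen after their values were seen.

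Genes within 500 kb of the edited sites were tested as a group of their own. RIC8B, downstream of RFX4 (chromosome 12, 106774595 to 106889316), was lower in full lines than in the other knockouts by -0.66 on day 9 (30.6 against 48.4 CPM) and -0.63 on day 8. NEK7, downstream of LHX9 (chromosome 1, 198156963 to 198322420), was higher by 0.55 on day 14 (31.2 ± 3.3 against 21.3 ± 1.4 CPM). PTPRG-AS1, next to FEZF2 (chromosome 3, 62260865 to 62369330), was higher by 0.81 on day 8 and 0.89 on day 7. PAUPAR, a noncoding gene beside PAX6 (chromosome 11, 31812307 to 32002405), was higher by 2.26 (1.14 against 0.237 CPM). LHX5-AS1 (chromosome 12, 113472003 to 113480624) was at 195 ± 14 CPM in LHX5 full lines on day 5 against 21.9 ± 5.7. On day 6 this excess was absent, and the difference of -1.06 (SE 0.83) did not pass. Full lines then lay at 42.35 ± 1.21 CPM, the other knockouts at 88.35 ± 87.38 and wild type at 42.05. Adjusted over the neighbours alone, strategies differed for 2 of 4 genes at FEZF2, 0 of 16 at LHX5, 1 of 12 at RFX4, 1 of 4 at OTX1, 1 of 7 at PAX6 and 1 of 4 at LHX9. Over all genes, PTPRG-AS1 on day 7 (edgeR adjusted p = 0.0128), LHX5-AS1 on day 5 (edgeR adjusted p = 0.0297) and RIC8B on day 8 (edgeR adjusted p = 0.0183) passed, besides WDPCP. Antisense and overlapping genes are uncertain, since the strand setting of the counting is not given in the sources used here. At PAX6 the count was 0 without B02 or C03, and it was 2 at RFX4 without B04 and 2 at LHX9 without A04.

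Developmental time moved most of the transcriptome. Between the days titled 3 and 5 of the LHX5 series (10 libraries per day), several targets of FGF signalling fell. For the later day the time field gives day 6. DUSP6 went from 93.0 ± 26.2 to 1.13 ± 0.37 CPM (log2 -6.38, SE 0.22), ETV5 from 94.3 to 2.59 CPM and SPRY4 from 244 to 13.6 CPM. SMAD7, an inhibitor of TGF-beta signalling, fell by 6.24 and the neural crest and pluripotency gene FOXD3 by 5.36. NANOG went from 118 to 6.91 CPM. CUZD1 rose from 17.8 ± 5.5 to 1659 ± 292 CPM (6.53, SE 0.22), IGFBP5 from 14.4 to 1154 CPM, and WFIKKN2 by 7.84 (SE 0.63). Of 24 S phase genes 23 fell, including CDC6 (175 to 46.0 CPM), and adjusted p = 0.0735 with an estimated correlation for that list. Of 24 pluripotency genes 20 fell and 1 rose (adjusted p = 0.159 with an estimated correlation), and of 20 FGF and ERK response genes 13 fell and 5 rose (adjusted p = 0.0735 with an estimated correlation). Counts adjusted over the list alone were equal. edgeR called 16803 of 24061 genes, 9099 higher and 7704 lower, and of the 13 lists that passed camera none was kept with an estimated correlation.

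Between days 5 and 7 of the FEZF2 series, forebrain and midbrain genes rose together. LMX1A, a roof plate and midbrain factor, went from 0.0478 to 20.4 CPM (8.61, SE 0.24), LHX5 from 1.01 ± 0.33 to 184 ± 20 (7.51, SE 0.13), FEZF1 from 2.01 to 159, SHISA2 from 8.17 to 436 and SIX3 from 1.09 to 44.6. CYP26A1, which degrades retinoic acid, went from 0.807 ± 0.288 to 189 ± 31 CPM. TDGF1, a Nodal co-receptor of pluripotent cells, fell from 221 ± 9 to 3.94 ± 6.82 CPM (-6.04, SE 0.66), and NPTX1 from 290 ± 75 to 4.38 ± 1.61. Of 22 anterior plate genes 17 rose and 2 fell (adjusted p = 0.0209 with an estimated correlation), and of 17 diencephalon and midbrain genes 11 rose and 4 fell (adjusted p = 0.00166 with an estimated correlation). All 20 cholesterol synthesis genes fell (mean -1.52, adjusted p = 0.00115 with an estimated correlation). All 12 heat shock genes fell, such as HSPH1 (-1.15; adjusted p = 0.0312 with an estimated correlation). Of 22 pluripotency genes 19 fell, with POU5F1 from 621 to 124 CPM (adjusted p = 0.0209 with an estimated correlation). Of 25 axon guidance genes 19 rose, with NRP2 from 98.8 to 859 CPM (adjusted p = 0.00742 with an estimated correlation). Counts adjusted over the list alone were equal. edgeR called 15833 of 24252 genes, 8155 higher and 7678 lower.

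Between days 6 and 8 of the RFX4 series, most pluripotency genes tested fell. TDGF1 went from 293 ± 80 to 0.489 ± 0.698 CPM (-9.15, SE 0.48) and SERPINB9 from 308 to 1.65. Of 22 pluripotency genes 19 fell and 3 rose (adjusted p = 0.0343 with an estimated correlation). EGR1 rose from 35.9 to 263 CPM, EGR3 from 0.802 to 71.9 and FOS from 2.21 to 23.6. Of 20 FGF and ERK response genes 14 rose and 3 fell, among the latter PHLDA1 (168 to 13.5 CPM; adjusted p = 0.0343 with an estimated correlation). Of 24 axon guidance genes 19 rose, with EPHA4 from 31.4 to 643 CPM (adjusted p = 0.0343 with an estimated correlation). All 24 S phase genes rose, with CDC6 from 60.3 to 196 CPM (adjusted p = 0.133 with an estimated correlation). DBX1, a progenitor homeobox factor, rose by 8.52 (SE 0.37) and VWF from 1.24 to 139 CPM. Counts adjusted over the list alone were equal. edgeR called 15526 of 24270 genes, 6988 higher and 8538 lower.

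Between days 7 and 9 of the OTX1 series, dorsal telencephalon genes rose. EMX2 went from 3.0 to 78.3 CPM (4.70), DMRTA2 rose by 5.34 (SE 0.32), and PAX6 went from 55.0 to 221 CPM (2.02). NR2F1 went from 0.874 to 33.7 CPM and the Notch effector HES5 from 0.428 to 24.97. NOS2 rose from 1.48 to 231 CPM (7.24, SE 0.25). The epithelial cadherin CDH1 fell from 151 ± 47 to 1.18 ± 1.37 CPM (-7.14, SE 0.29), CUZD1 from 285 to 2.11 and POU5F1 from 87.7 ± 13.7 to 1.73 ± 0.50 (-5.64, SE 0.09). Of 20 dorsal telencephalon genes 15 rose and 5 fell (adjusted p = 0.00442 with an estimated correlation), and of 18 pluripotency genes 14 fell and 1 rose (adjusted p = 0.00081 with an estimated correlation). All 24 ribosomal protein genes fell, with RPL3 from 1724 to 904 CPM (adjusted p = 0.168 with an estimated correlation). The median share of reads outside features was 36.1% on day 7 and 48.6% on day 9. Counts adjusted over the list alone were equal. edgeR called 14813 of 23229 genes, 7495 higher and 7318 lower. Each of the 4 intervals came from a different series, so differences between intervals were not tested.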

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

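The tests of whether a knockout effect differed between days were chosen after the results of single days were seen. In the FEZF2 series the effect of knockout against wild type differed between days 5, 6, 7 and 8 for 68 genes (edgeR F test of the interaction, adjusted over all genes), with 3727 at an unadjusted p under 0.05. RAC3, a small GTPase, was at -0.46, -0.52, 0.57 and -0.04 on days 5 to 8 (edgeR adjusted p = 0.00536). NDUFB7, a subunit of mitochondrial complex I, was at -0.48, -0.65, 0.57 and 0.11, and ID3, a BMP target, at -0.75, -0.68, 0.71 and 0.02. The ribosomal protein gene RPS27 was at -0.74, -0.37, 0.43 and -0.34. Days 5 to 7 each rest on 1 wild-type library, so the direction on each of these days is set by a single control. That library held 13.7% of reads outside features on day 5 and 14.9% on day 6, the lowest of its collection on both days (medians 19.1% and 17.9%). On day 7 it held 24.2%, above the median of 19.9%. The signs of these 4 genes turn between the same days, and whether the share accounts for this was not tested.

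In the LHX5 series the effect differed between days for 1 gene, L1CAM, a cell adhesion molecule of growing axons (edgeR adjusted p = 0.0330). L1CAM was at -0.17, -0.16, -0.24 and 0.50 on days 3 to 6. edgeR called 0 genes in the RFX4 series (361 at an unadjusted p under 0.05) and 0 in the OTX1 series (2089 at an unadjusted p under 0.05). No other tool was run on the difference between days.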

How the results depend on the processing

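Settings chosen after the data were seen are 5: the share of reads outside features as a covariate, the LHX5 libraries under 30% of such reads left out, FEZF2 libraries of the wild-type lane alone, all days with the clone as a random replicate block, and RFX4 time without the day 6 library of full clone B04. All others were planned, and the cause of a change was not tested unless the setting itself removed libraries or genes. Counts of called genes stayed within 1.5 times in 275 of the fits over all comparisons and settings and moved further in 131. Log2 values of named genes kept direction and side of the threshold in 7512 cases, lost the call in 300, gained it in 34 and changed sign in 76. Of list results, 1374 were the same, 196 lost the call and 4 changed sign. Comparisons over time kept their counts in every setting run, whereas knockout and strategy counts moved often. OTX1 days 8 and 9 had the fewest reads and the largest share outside features, which limits the calls of low genes there.

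With DESeq2, counts were 27 (FEZF2), 252 (LHX5), 1 (RFX4), 16 (OTX1) and 1 (LHX9) for knockouts, and 219 (FEZF2), 15 (LHX5), 47 (RFX4), 37 (OTX1), 2 (PAX6) and 4 (LHX9) for strategies. With RLE scaling, RFX4 strategies gave 2. Without the low-count filter, knockouts gave 12 (FEZF2) and 20 (OTX1), strategies 25 (FEZF2), 4 (RFX4), 15 (OTX1) and 2 (LHX9), and LHX9 neighbours 2. With Salmon counts, knockouts gave 3 (FEZF2) and 2 (PAX6), strategies 2 (FEZF2), 0 (LHX5) and 2 (RFX4), and OTX1 neighbours 0. With Salmon counts the sign also changed for RFX1 (-0.080), OTX2 (0.019), C3orf14 (-0.40 in FEZF2 strategies), WDPCP (-0.30 in OTX1 strategies), RPS23 (0.19 in LHX5 time) and HSPA4L (-0.30 in OTX1 time). Of all changes of sign, that of RPS23 was the one past the threshold both ways (edgeR adjusted p = 0.00041 with Salmon counts). LHX2 in LHX9 knockouts, close to 0, turned to 0.0044 (DESeq2), 0.0034 (RLE) and 0.012 (no filter). On the TPM scale, the target differed from wild type by -3.65 (full), -0.40 (exon) and 0.87 (stop) for FEZF2, -1.97 (full) and -1.29 (stop) for RFX4, 1.83 (full) for PAX6, and -3.22 (full), -0.82 (exon) and -1.45 (stop) for LHX9.

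Against wild type, full clones alone gave 2 (FEZF2), 4291 (LHX5), 405 (RFX4), 3 (OTX1), 1 (PAX6) and 2 (LHX9) genes, with PAX6 at 0.60 and LHX2 at 0.25. Exon clones alone gave 0 (LHX5), 1 (RFX4), 1 (PAX6) and 55 (LHX9), with FEZF1 at 0.062 and RFX3 at 0.020. Stop clones alone gave 212 (LHX5), 1 (RFX4) and 107 (OTX1), with FEZF2 at 0.65, RFX2 at 0.12, PAX2 at -0.022 and LHX2 at 0.015. Knockout libraries alone gave 586 (FEZF2) and 0 (LHX5) genes for strategies. Adding wild types of other collections gave 38 (LHX5), 39 (OTX1) and 1023 (PAX6) genes, with FEZF1 at 0.11, RFX2 at 0.17 and OTX2 at 0.11. With the share of reads outside features as a covariate, knockouts gave 8 (FEZF2) and 95 (LHX5), strategies 6 (FEZF2), 30 (LHX5) and 6 (RFX4), and PAX6 neighbours 0. Signs changed for OTX2 (0.15), LHX2 (0.37) and LHX5 between strategies (-0.013). The lists that changed sign lost their call: FEZF2 knockout against wild type: list cell cycle S phase (adjusted p = 0.659), FEZF2 knockout against wild type: list ribosomal proteins (adjusted p = 0.0876) and LHX5 knockout against wild type: list ribosomal proteins (adjusted p = 0.905). FEZF2 knockout against wild type: list anterior neural plate and eye field also lost its call (adjusted p = 0.424), while LHX5 knockout against wild type: list anterior neural plate and eye field (adjusted p = 1.01e-09) and LHX5 knockout against wild type: list Notch targets (adjusted p = 5.97e-08) kept theirs. These are values at the preset correlation. Without the covariate, both of these LHX5 lists lost the call with an estimated correlation (adjusted p = 0.0641 and 0.0554). Without the LHX5 libraries under 30%, knockouts and strategies gave 0 each, with LHX5 at -0.36 between strategies. In the wild-type lane alone, FEZF2 was at 0.30, since no full clone was left.

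Other days gave other genes. On day 3, LHX5 knockouts gave 4 genes and strategies 0, with KCP -0.22, PTPRN2 -0.27, HCN4 -0.23 and RAB15 -0.028, and LHX5 at -0.53 between strategies. On day 4, LHX5 knockouts gave 3, strategies 0 and neighbours 1. Signs changed there for LHX1 (-0.21), HAS3 (-0.14), LFNG (-0.033), KCP (-0.22), LYN (-0.075), RAB15 (-0.066), SLC13A3 (0.046) and NOTCH1 (-0.16), and between strategies for ZNF528 (0.095) and LHX5 (-0.099). On day 5, knockouts gave 1177 (FEZF2) and 0 (LHX5), FEZF2 strategies 37, and neighbours 0 (FEZF2) and 1 (LHX5). In LHX5 knockouts of day 5, LHX1 was at -0.12, LFNG -0.092, PTPRN2 -0.12, HCN4 -0.20, RAB15 -0.082, MYCBPAP 0.15, SLC13A4 0.054 and NOTCH1 -0.12, with ZNF528 at 0.092 between strategies. On day 6, FEZF2 knockouts gave 1, and strategies and neighbours 0 each for FEZF2 and RFX4, with FEZF1 at 0.14, RFX3 at 0.20 and RFX1 at -0.039. On day 7, knockouts gave 1 (FEZF2) and 0 (OTX1), strategies 109 (FEZF2), 0 (RFX4) and 10 (OTX1), and FEZF2 neighbours 1. FEZF2 (0.12), FEZF1 (0.19), RFX1 (-0.15), CRX (0.32) and GRIK3 (0.18) changed sign there, as did C3orf14 (-0.075) and OTX1 (0.16) between strategies. On day 8, knockouts gave 1 (RFX4) and 2 (OTX1) and OTX1 strategies 10. RFX3 (0.071), RFX2 (0.012) and H2BC21 (0.23) changed sign, as did RFX4 (0.11) and OTX1 (0.063) between strategies. All days in 1 edgeR fit gave 1 (FEZF2), 8 (LHX5) and 2 (OTX1) for knockouts, with RFX3 at 0.043 and RFX1 at -0.0030.

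With the line as a replicate block, the comparison FEZF2 later against earlier day gave 15092 genes, LHX5 later against earlier day 16765, RFX4 later against earlier day 15587 and OTX1 later against earlier day 13090. The block ended the call of RPS27 in FEZF2 time (0.31, edgeR adjusted p = 0.0773). In OTX1 time it ended the camera calls of neurogenesis (adjusted p = 0.0641) and SHH target lists (adjusted p = 0.133), and it changed no other call. All days with limma voom and the clone as a random replicate block gave 3 (FEZF2), 14 (LHX5), 1 (RFX4) and 2 (OTX1) genes for knockouts, with RFX3 at 0.037 and RFX1 at -0.0090. RFX4 time without the day 6 library of B04 gave 16832 genes.

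Leaving out 1 library or line at a time, knockout counts ranged from 0 to 191 for FEZF2, 0 to 4361 for LHX5, 0 to 13 for RFX4, 5 to 44 for OTX1 and 0 to 6 for LHX9, and stayed at 0 for PAX6. The highest counts came without wild-type library 3 for FEZF2, exon B05 for LHX5, exon C06 for RFX4, full D02 for OTX1 and stop A09 for LHX9. Strategy counts ranged from 1 to 4 (FEZF2, highest without B11), 0 to 7 (LHX5, without B05), 1 to 458 (RFX4, without B12), 2 to 178 (OTX1, without E06), 0 to 2 (PAX6, without A11) and 0 to 1 (LHX9). Neighbour counts ranged from 1 to 2 for RFX4 and LHX9 and 0 to 1 for PAX6. LHX5 between LHX5 strategies ranged from -0.27 (without B02) to 0.60, OTX2 in OTX1 knockouts from -0.069 to 0.021 (without D02) and LHX2 in LHX9 knockouts from -0.18 to 0.095. The camera adjusted p of FEZF2 knockout against wild type: list ribosomal proteins ranged from 1.89e-22 to 0.648, and the list turned upward without wild-type library 2. Time counts ranged from 14991 to 15611 (FEZF2), 15785 to 16729 (LHX5), 14368 to 16794 (RFX4) and 13961 to 14650 (OTX1).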

Other observations

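The tests of neighbouring genes, chromosome 20, the anterior neural plate list and genes that rose early and fell late were chosen after the results were seen, while the splits of the samples were planned. Some genes rose over early days in 1 series and fell over later days in another. Of 21927 genes tested in both series, 114 rose by at least 2 on the log2 scale from day 3 to 5 in the LHX5 series and fell by as much from day 7 to 9 in the OTX1 series. Independent lists would share 28.9 genes. The other 3 combinations of direction also shared more genes than independent lists would, so the excess is not special to this direction. DAZL, an RNA-binding protein best known in germ cells, went from 0.657 to 15.4 CPM early and from 25.5 to 0.743 CPM late. CYP26A1 went from 0.868 to 12.6 and from 143 to 4.89 CPM, TGFB2 from 0.482 to 8.39 and from 46.8 to 2.01, and PPP1R1B, a phosphatase inhibitor of striatal neurons, from 9.51 to 132 and from 12.7 to 0.434. Both changes passed for each of these genes (edgeR adjusted p of at most 2.66e-10 early and 5.78e-11 late).

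Cholesterol synthesis genes moved both ways over time. All 20 fell from day 6 to 8 in the RFX4 series (mean -0.90, adjusted p = 0.201 with an estimated correlation), whereas 19 of 20 rose from day 7 to 9 in the OTX1 series (mean 0.70, adjusted p = 0.110 with an estimated correlation). In the FEZF2 series from day 5 to 7, 14 of 19 cortical hem and choroid plexus genes rose (adjusted p = 0.00136 with an estimated correlation), as did 22 of 31 ciliary and RFX target genes (adjusted p = 0.00977 with an estimated correlation). From day 3 to 5 in the LHX5 series, 15 of 18 interferon response genes rose (adjusted p = 0.0735 with an estimated correlation). Adjusted over the list alone, the counts were equal.

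Genes beside the edited interval differed in full deletion lines. Reads counted by position outside annotated transcripts remain a candidate explanation for WDPCP, since the Salmon counts of annotated transcripts gave -0.30 against 2.63, and for C3orf14 (-0.40 against 0.58). They do not account for the others, which kept their size in Salmon counts: PTPRG-AS1 at 1.21 on day 7, LHX5-AS1 at 3.17 on day 5, RIC8B at -0.64 on day 8, PAUPAR at 1.94 and NEK7 at 0.57. Differences of this size around any locus were argued against at 5 of the 6 targets, where under 5% of 1000 random loci held a p as small, while at LHX5 on day 6 the share was 0.924. The OTX1 value rests on WDPCP, which turned in Salmon counts. ENSG00000286480, whose place is not known here, was not part of that value and lay at 4.90 in Salmon counts on day 9. The FEZF2 value rests on PTPRG-AS1 on day 8, where all full clones shared a lane without wild-type libraries. PTPRG-AS1 also differed on day 7, when all libraries shared a single lane. Loss of regulatory DNA and transcription past the edited end stay open as biological explanations, and neither was tested.

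The LHX9 stop A09 library differed from the other 9 on chromosome 20 in all 6 windows of 10 Mb, which lay outside the range of those libraries. A broad shift of the library was argued against, since the median window on other autosomes moved 0.201 times as much as on chromosome 20 (0.0622 against 0.309, over 212 windows), though 7 of them were as large as the smallest on chromosome 20. A loss in the short arm with a gain of the long arm is a candidate explanation: 90.5% of genes lay on the side it predicts. That share comes from the windows that gave the pattern, and it replaced a count of windows after its outcome was visible, so it cannot support the explanation. It stays open, and no biological explanation was tested.

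The anterior neural plate list was lower in all 9 LHX5 knockout libraries on each day. A shift in developmental timing stays open. On day 6, the slope on the day 5 to 7 changes of the FEZF2 series gave 0.457 of the list difference (-0.25 of -0.54). The slope on the day 3 to 5 changes of the LHX5 series gave 0.051 of the day 6 difference (-0.0278). On days 3 to 5, the slope on the day 3 to 5 changes gave a share of at most -0.028, but the list changed too little over that interval to exclude it. Wild-type libraries that stand apart stay open: an exact two-sided permutation test on day 6 gave p = 0.00455, the smallest that 220 splits can give, but such libraries would give the same value. An effect of any edited line against the parental line would lower the list in other targets too. Of their 13 comparisons, 10 had means above 0, up to 0.70, but most were on days 7 to 14, later than those of LHX5. On days shared with LHX5, the mean was -0.84 (FEZF2 day 5), -0.25 (FEZF2 day 6) and 0.24 (RFX4 day 6). Days of 1 target also share most clones, so the count of comparisons cannot decide. An effect of any edited line stays open, and 1 comparison was as low, FEZF2 day 5 (-0.84 against -0.54), where the wild-type library stood apart. An effect of the loss of LHX5 itself stays open beside it, as a hypothesis found on these same data.

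Splits of the same samples were compared with the real grouping, 100 for each comparison. For LHX5 knockouts, 3 of the 100 splits, the real one included, called at least the real 23 genes. This was under the bound set beforehand, which argues against chance for the grouping as a whole without excluding it. The splits also mixed the 3 strategies, within which spread was estimated, so they do not isolate the wild-type label. The highest other split called 5434. That split, with full B02, full E04 and exon A01 placed as wild type, points to a structure of the samples that the groups do not describe. These 3 libraries had the lowest shares of reads outside features, at 23.3%, 28.0% and 26.2% against 32.8% to 46.3% in the others, and wild types lay at 37.7%, 43.6% and 40.7%. For FEZF2 knockouts and PAX6 strategies the real count was 0, which every split reaches, so these splits say nothing of chance. The highest other FEZF2 split called 1920, which also points to a structure. For the other strategies, chance could not be excluded as the source of counts this small, which says nothing of the single genes called and their adjusted p. As many genes came from 14 splits for FEZF2 (real 1, highest other 2), 14 for LHX5 (1, 3562), 21 for RFX4 (1, 2884), 8 for OTX1 (2, 87) and 8 for LHX9 (1, 9). The highest PAX6 split called 6, and 100 splits reached the real 0 for each of FEZF2 knockouts and PAX6 strategies. The high counts for LHX5, RFX4 and OTX1 again point to a structure among clones. For time, days were exchanged within lines, and only the real one of the 100 splits reached its count. This argues against chance, though 100 splits cannot give a share under 1 in 100. The real count stood against the highest other at 15833 against 12859 (FEZF2), 16803 against 13732 (LHX5), 15526 against 11833 (RFX4) and 14813 against 11263 (OTX1). Splits that exchange few lines keep most of the difference between days.

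Some libraries lay farther from the median of their collection than others. Full clone B04 of RFX4 day 6 lay 4.29 times as far as the median library, exon B05 of LHX5 day 6 2.56 times, full B01 of PAX6 2.22 times and full D02 of OTX1 day 9 2.19 times.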
